A study of Mus musculus with 33 samples.

How the data were processed

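Enteric neural crest cells (ENCCs) carrying YFP under Wnt1-Cre were sorted from mouse guts at embryonic day 14.5 and cultured on fibronectin, per the labels' protocols. The cells of 1 gut were divided over 2 wells, and 1 of the wells received 50 ng/ml GDNF. How long the cells were cultured is not given in the sources used here. Whole guts of wild-type embryos of the same age served as the tissue for comparison. RNA was labelled with biotin and read on 33 Affymetrix arrays, 25 of ENCCs and 8 of whole guts. The titles carry 9 replicate numbers for ENCCs, which are read here as gut numbers, and name 2 batches, with 17 arrays in batch 1 and 16 in batch 2. Of the 18 ENCC RNAs, 7 were hybridised in both batches, and arrays of 1 RNA were counted as 1 replicate. The guts are separate samples in the labels, which do not say whether embryos shared a litter or whether a whole gut RNA came from 1 embryo. If RNAs were pooled, n = 8 would count pools, and their SD would not be a spread between embryos.

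The submitters' processing notes name RMA, a method that corrects the background, normalises and summarises the probes of each set on a log2 scale, and give no version. The deposited values are not on that scale. Each deposited value is a score made by ranking an array, which is read here from the values and not from the labels: the 45101 sorted values of each array equal the normal quantiles of rank over n plus 1, with a largest deviation of 5e-06, so that each array runs from -4.084 to 4.084 with a median of 0. The values also carry the mark of an earlier step. The mean of a probe set over the 7 RNAs hybridised in both batches varied over probe sets with an SD of 0.0585 in batch 1 and 0.117 in batch 2, where independent arrays of unit variance would give 0.378. The smallest eigenvalue of the covariance of those 7 arrays was 0.0215 in batch 1, against 0.727 for the next. Such values arise when each probe set is centred and scaled within a batch on those 7 arrays before the arrays are ranked. Which program did so is not given in the sources used here. These steps were read from the values, and no label records them.

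The scores limit what can be said. The level of a gene and the brightness of its probe sets are not kept, so no fold change is given, no filter on dim probe sets was possible, and levels of different genes are not compared. The rule for named genes orders them by their difference in score, which depends on the spread of their probe sets among ENCC arrays and is not an order of fold. The mean over probe sets that disagree is smaller, so the rule can favour genes with 1 probe set. Between ENCC arrays, a difference of 1 is about 1 SD of the spread of a probe set among them. The 7 RNAs used for the scaling include treated and untreated wells, so this spread holds any GDNF difference. The scaling thus holds down large GDNF differences, and their sizes do not tell how large a response was. By construction the mean score over the 7 RNAs hybridised in both batches lies near 0, while single ENCC scores do not. A score for whole gut ranks, within its array, how far the tissue lies from the ENCCs relative to their spread. Ranking gives whole gut arrays the same distribution as ENCC arrays, so this score is not a number of ENCC SDs. How far ranking also narrows the SD among whole guts is not known. Because the median of every array is 0, a shift of all genes in 1 direction is not kept. The number of arrays limits the precision.

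Probe sets were named from the platform annotation given for this work. Of all probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none. The 64 control probe sets, 13 of them named, were left out, which left 34945 probe sets for 18193 genes. For 34741 of these probe sets the gene identifier was found in a gene table of the mouse reference assembly, and 0 symbols needed an update. The score of a gene was the mean of its probe sets, of which 9010 genes had several and 9183 had 1. Some genes of the rule for named genes are not reported here.

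The comparisons and tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined, on the assumption of log2 values. Because the unit was another, 3 choices departed from that design after the values and first call counts had been seen. Probe sets of a gene were averaged, since the brightest could not be found. The spread was moderated without a trend in brightness. No minimum fold was asked of ENCCs against whole gut.

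For GDNF, the score of the untreated well was subtracted from that of the treated well of the same gut, inside a batch, and guts 3, 8 and 9, present in both batches, entered as the mean of their 2 differences. Limma (version 3.58.1, with statmod 1.5.0 in R 4.3.3) was fitted to the 9 differences with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. That a gut gave both wells comes from the labels' treatment protocol, and which wells belong together was read from the replicate numbers. As a check, the scores of the 2 wells of a gut, as deviations from their group means in batch 1, correlated over genes at 0.136, 0.107, 0.277, 0.284, 0.239, 0.274, 0.161 and 0.030 in guts 1, 3, 4, 5, 6, 7, 8 and 9. In 5 of these 8 guts the treated well of another gut correlated better, at 0.234, 0.272, 0.299, 0.216 and 0.171 for guts 3, 6, 7, 8 and 9, so this check leaves the pairing open. Xist was below 0 in both wells of guts 3 and 5 and in no other ENCC well, and the mean of the Y-linked genes was above 0 in both wells of gut 3 alone, so for these 2 guts the wells go together as numbered; for the other 7 it does not tell. ENCCs were compared with whole gut inside batch 2, where all whole guts lie. There 4 embryos (guts 2, 3, 8 and 9), each the mean of its 2 wells, were set against 8 whole guts, and untreated and treated cells were also set against whole gut apart, in a fit of 3 groups. These fits hold cultured sorted cells on the one side and uncultured tissue on the other.

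Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 37 lists with at least 3 measured genes. Camera with an estimated correlation and fry were run beside it. An exact test was added after the results of camera had been seen: the mean difference of a list minus that of all other genes was taken in each gut, and the signs of the 9 values were changed in all 512 ways, two-sided. The smallest p it can give is 0.00391. Calls shared between comparisons were tested with Fisher's exact test, two-sided. Genes named are the 10 with the largest rise and the 10 with the largest fall among those called with 1 sign in all 9 guts, or called with no overlap between the 4 embryos and the 8 whole guts. To these were added up to 2 members at each end of a described list by the moderated statistic, and a set of genes of RET signalling and of gut cell types.

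The fits were tested on simulated data with 200 of 18193 genes changed, in 5 draws. With 9 pairs, limma recovered 0% of the genes changed by 0.5, 13.1% of those changed by 1 and 67.6% of those changed by 1.5, and false calls were 4.52% of the calls at the last size. With 4 against 8 samples the recovered shares at 0.5, 1 and 1.5 were 0.100%, 54.9% and 89.5%. False calls there were 50.0% of only 2 calls, 5.99% and 3.87% of the calls. With no gene changed, 0 genes were called in either design. The data called far larger shares of genes, 31.5% for GDNF and 54.1% for ENCCs against whole gut. The adjustment of p-values is less strict when more genes change, so the recovered shares can be too low for the data. The simulation gave both groups the same SD for a gene, while in the data embryos often varied more than whole guts (for Ret, 0.59 against 0.04). It therefore does not show how many false calls the unequal spreads bring in ENCCs against whole gut. In 50 simulated sets without a shifted list, camera called a list in 0. The genes were simulated as uncorrelated, so these sets cannot show false calls of lists whose genes move together. In the GDNF data the estimated correlation reached 0.870, in the list of the G2/M phase.

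Alternatives covered the choice of probe set, the moderation, fits without pairing, within each batch and on all arrays, each sample left out in turn, and the untreated array of gut 3 in batch 2 left out. The closing section gives their effect. Data were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.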

Results

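The series profiled ENCCs, the migratory precursors of the enteric nervous system, with and without GDNF, the ligand that acts through the receptor tyrosine kinase RET and its co-receptor Gfra1. It also profiled whole gut of the same embryonic age, 14.5 days. Cells of 9 guts gave 9 untreated and 9 treated RNAs, which were read on 12 and 13 arrays, and 8 whole guts were read on 1 array each. All values are scores within an array, scaled on the ENCCs of its batch, and differences are in these units, not folds. For the 7 RNAs read in both batches, the correlation of the scores over probe sets between batches was 0.117 to 0.325 with a median of 0.296. In 2 of the 7, another RNA of the same group correlated better, at 0.388 against 0.117 for the untreated well of gut 3 and at 0.268 against 0.247 for the treated well of gut 8. Between arrays of different whole guts it was 0.902 to 0.952. These values are not like measures of agreement. Centring on ENCC arrays takes from them the profile they share, while whole guts keep their common difference from ENCCs.

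The first comparison asked which genes respond to GDNF in ENCCs. The lists of neuron and cholesterol synthesis genes lay above other genes, and those of p53 target, ribosomal protein and BMP and TGF-beta genes lay below. Camera called these 5 lists, but with an estimated correlation their adjusted p was 0.0542 to 0.247, and sign changes drawn at random called as many lists as the real data in 14 of 100 draws. The ribosomal protein list was fixed beforehand as a sign of RNA quality, and its shift of -1.01 ± 0.33 was below 0 in 9 of 9 guts. Whether this list follows RNA quality in these samples was not tested. Elavl3, an RNA-binding protein of neurons, rose by 2.04 ± 0.41 (SD, n = 9 guts), and Opcml, a cell adhesion protein of neurons, rose by 2.25 ± 0.64. Pde1b, a phosphodiesterase activated by calmodulin, rose by 2.21 ± 0.85. Ablim3, Sorcs2, Lrrc75b, Spns2, Dipk1a, Smap2 and Svop rose by 2.03 to 2.17. Among the genes with the largest falls, Ermap fell by 2.17 ± 1.70, Adss, an enzyme of adenine nucleotide synthesis, fell by 1.96 ± 0.80, and Tnfrsf12a, the receptor of the cytokine TWEAK, fell by 1.87 ± 0.57. Rtraf, Dnajb9, Svbp, Snx24, H2bc22, Ccn4 and Laptm4a differed by -1.91 to -1.78. These sizes are means over probe sets, each scaled on its own spread among ENCC arrays, so their order is not an order of fold. In batch 2 alone, with 4 guts, Elavl3 was at 1.95, Opcml at 2.17 and Ermap at -0.54. Each of these 20 genes had 1 sign in all 9 guts and an adjusted p of 0.00273 or lower.

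Limma called 5725 of 18193 genes (31.5%), 3321 higher and 2404 lower with GDNF. The median size of the difference among called genes was 1.12, against a median SD over guts of 0.84 across genes. Of all genes, called or not, 3247 (17.8%) had 1 sign in all 9 guts, which chance gives in 0.391% of genes. Of the called genes 3209 did, 2112 higher and 1097 lower. In batch 1 alone, with 8 guts, 5324 genes were called. In batch 2 alone, with 4 guts, limma called 0 genes, and 3516 passed an unadjusted p of 0.05. In guts 1, 4, 5, 6 and 7 limma called 2467 genes, 1725 higher and 742 lower, and 2393 of them (97.0%) had the same sign in the mean of guts 2, 3, 8 and 9. Across genes, which are not independent replicates, the differences of these 2 sets of guts correlated with r = 0.693 and rho = 0.674. The hybridisation control probe sets differed by -0.72 ± 0.99 between treated and untreated wells and were lower in 6 of 9 guts (exact sign change test, two-sided, p = 0.0703).

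**Figure D1:**
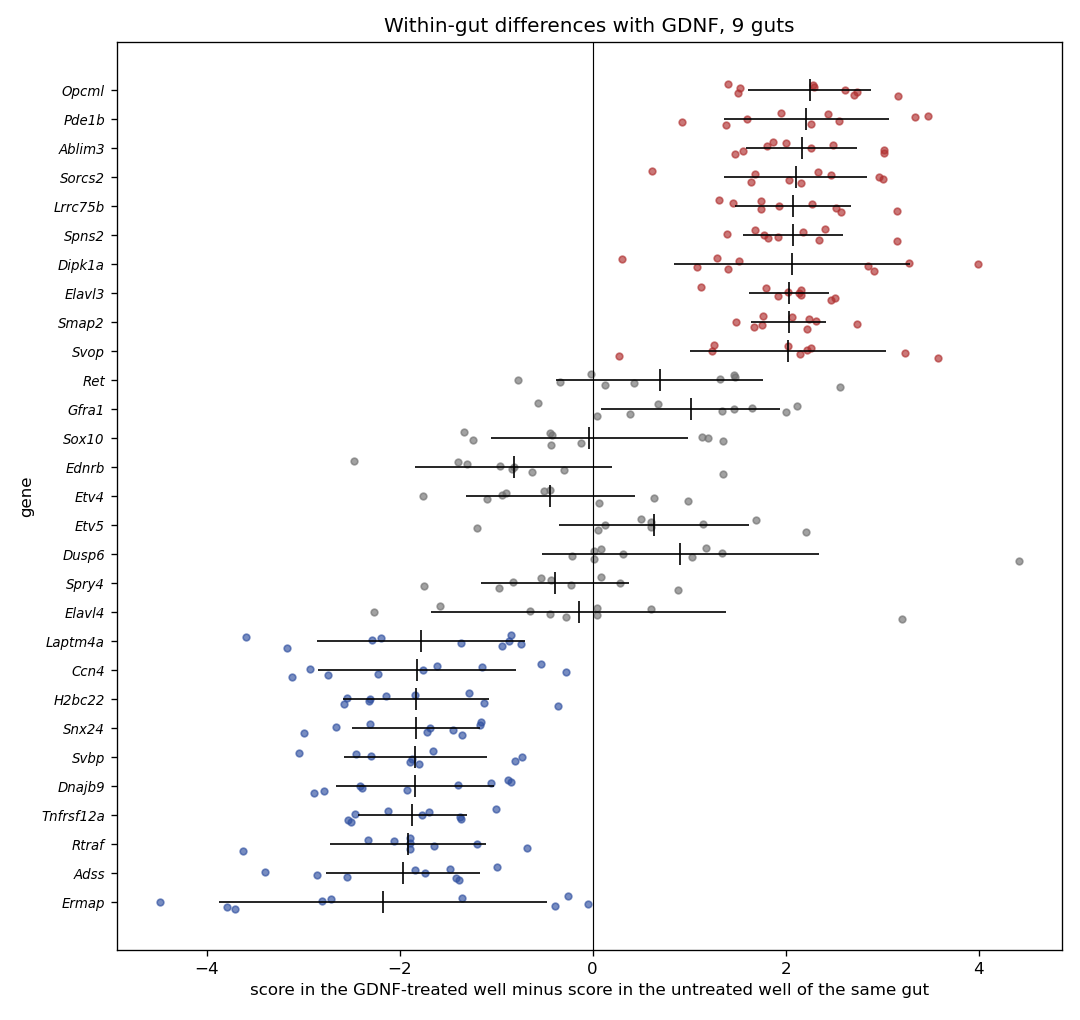
Difference in score between the GDNF-treated and the untreated well of the same gut (x axis, score units) for the genes with the largest rises and falls and for genes of RET signalling and ENCC identity (y axis). Points are the 9 guts, bars the mean and SD, red genes that rose, blue genes that fell and grey genes chosen beforehand; all 9 points of Opcml lie above 0 and all 9 of Ermap below.

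Ret itself did not pass the test, at 0.70 ± 1.07 (n = 9, limma adjusted p = 0.119). Its co-receptor Gfra1 rose by 1.01 ± 0.93 (adjusted p = 0.0166). The difference was 1.55 with the hybridisation controls as a covariate and 0.53, without a call, in batch 2 alone. Of the 9 measured GDNF family ligands and receptors, 3 rose and 2 fell, with the same counts adjusted over the list alone. Gfra4 rose by 1.26 ± 0.88 and Gfra2 fell by 0.98 ± 0.70, a call that ended with the hybridisation controls as a covariate (-0.69) and with its probe sets taken singly (-1.07). With its most reproducible probe set, the one that correlated best between batches, it lay at -1.58. The list did not move as a whole (camera adjusted p = 0.789). Of 16 genes of ERK feedback and ETV factors, 3 rose and 2 fell, also over the list alone. Spred3 rose by 1.52 ± 0.32 and Phlda1 by 1.62 ± 0.52, while Ccnd1, which encodes cyclin D1, fell by 1.24 ± 0.41. Etv4 was at -0.44 ± 0.88, Etv5 at 0.64 ± 0.99, Spry4 at -0.39 ± 0.77 and Dusp6 at 0.91 ± 1.44, of which none passed. Gut 1 alone had a Dusp6 difference of 4.42, and Etv5 passed without gut 3 (0.87, adjusted p = 0.0326). Spry4 passed with its most reproducible probe set, at -1.13, and 2 of its 4 probe sets had the other sign. The mean of this list was 0.09 and its median -0.29, and camera's adjusted p was 0.920.

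Of 18 ENCC progenitor genes 3 rose and 3 fell, with the same counts adjusted over the list alone, and the list did not move as a whole (camera adjusted p = 0.685). Phox2a, a transcription factor of autonomic neurons, rose by 1.41 ± 0.53 (n = 9). Sox2 fell by 1.46 ± 0.73 and Tfap2a, a factor of the neural crest, fell by 1.25 ± 0.36 (-0.73 in batch 2 alone). Sox10, a factor of progenitors and glia, was at -0.03 ± 1.03 (adjusted p = 0.952). The endothelin receptor gene Ednrb was at -0.82 ± 1.02 (adjusted p = 0.0602) and passed without gut 1, at -1.09 (adjusted p = 0.00530), without the doubted array of gut 3, that of the untreated well in batch 2 (-0.91), and in a fit of all arrays (-0.97). Gdnf was at 0.14 ± 1.33. Of 17 measured Hirschsprung disease genes, 8 rose and 2 fell, and 3 fell when adjusted over the list alone, with 8 rising there too. Nrg1 rose by 1.86 ± 0.45 and Dhcr7 by 1.71 ± 0.51, and Edn3 fell by 1.23 ± 0.84 (camera adjusted p of the list 0.377). With the most reproducible probe set Edn3 lay at -1.94, and in batch 2 alone at -0.43.

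Most genes of enteric neurons rose. Of 24 measured, 19 rose and 0 fell, and 20 rose when adjusted over the list alone. Elavl3 led them, and Ina, which encodes the neurofilament protein internexin, rose by 1.88 ± 0.34 (n = 9). Elavl4 was at -0.15 ± 1.53 and Elavl2 at -0.17 ± 1.07, neither of which passed. The list lay 1.19 ± 0.24 above all other genes and above them in 9 of 9 guts. Camera called it at an adjusted p of 2.6e-10, with an adjusted p = 0.0542 with an estimated correlation and 0.0145 in the exact sign change test. Ribosomal protein genes, fixed beforehand as a sign of RNA quality, moved the other way in the same 9 guts (-1.01). Whether the share of neurons among the sorted cells changed was not tested. Of 21 genes of transmitters and neuropeptides, 8 rose and 2 fell, also over the list alone. Slc18a2, the vesicular monoamine transporter, rose by 1.87 ± 0.27 and the peptide gene Vip by 1.77 ± 0.34, while the peptide gene Npy fell by 1.46 ± 1.29. This list passed the exact test (adjusted p = 0.0145) but not camera (0.134).

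Genes of cholesterol synthesis rose in 16 of 17 measured and fell in 0, with the same counts adjusted over the list alone. The mevalonate pathway enzymes Pmvk and Mvd rose by 1.70 ± 0.22 and 1.60 ± 0.31 (n = 9). Hsd17b7 was at 0.25 ± 1.13, with gut 6 at -2.09. The list lay 1.23 ± 0.21 above other genes, in 9 of 9 guts (camera adjusted p = 9.7e-10, adjusted p = 0.114 with an estimated correlation, exact adjusted p = 0.0145), where ribosomal protein genes lay at -1.01. Of 19 genes of glycolysis and hypoxia 9 rose and 1 fell, and 10 and 3 when adjusted over the list alone. The glycolytic enzymes Hk1 and Pgam1 rose by 1.77 ± 0.57 and 1.46 ± 0.64. The list lay 0.54 ± 0.60 above other genes, in 8 of 9 guts (camera adjusted p = 0.0289, adjusted p = 0.835 with an estimated correlation, exact adjusted p = 0.0263). Camera no longer called it without gut 3 (adjusted p = 0.0685) or gut 7 (0.0623).

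Targets of p53 and genes of apoptosis fell in 14 of 18 measured and rose in 1, with the same counts adjusted over the list alone. The growth-restraining gene Btg2 fell by 1.58 ± 0.41 (n = 9) and the stress-response gene Sesn2 fell by 1.48 ± 0.49. The gene that rose was Bcl2, which encodes an inhibitor of apoptosis, at 0.82 ± 0.56. The median of its probe sets taken singly did not pass (0.76), its most reproducible one lay at 1.30, and batch 2 alone gave 0.29. The list lay at -1.09 ± 0.39 against other genes and below them in 9 of 9 guts (camera adjusted p = 6.3e-07, adjusted p = 0.247 with an estimated correlation, exact adjusted p = 0.0145). In gut 1 it lay at -0.13. Ribosomal protein genes, fixed beforehand as a sign of RNA quality, fell in 8 of 10 measured and rose in 0. They fell in 10 when adjusted over the list alone. Rps19 was at -1.31 ± 0.80 and Rpl7 at -1.24 ± 0.69. As a group they lay at -1.01 ± 0.33, below other genes in 9 of 9 guts (camera adjusted p = 8.1e-05, adjusted p = 0.198 with an estimated correlation, exact adjusted p = 0.0145).

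BMP and TGF-beta genes fell in 9 of 20 and rose in 0, with the same counts adjusted over the list alone. Bambi, a decoy receptor that dampens TGF-beta signalling, was at -1.64 ± 0.36 (n = 9), and Tgfbi, a gene induced by TGF-beta, at -1.64 ± 0.78. The list lay at -0.74 ± 0.20 in 9 of 9 guts (camera adjusted p = 1.8e-04, adjusted p = 0.0542 with an estimated correlation, exact adjusted p = 0.0145), in the same direction as the ribosomal protein genes (-1.01). Genes of the Hedgehog pathway fell in 6 of 12 and rose in 0, and fell in 8 when adjusted over the list alone. Hhip, a target and inhibitor of the pathway, fell by 1.18 ± 0.64 and the transducer Smo fell by 1.13 ± 0.60. As a group they lay at -0.61 ± 0.29 (camera adjusted p = 0.0120, adjusted p = 0.361 with an estimated correlation, exact adjusted p = 0.0145). Genes of gut mesenchyme, a cell type the sort was meant to remove, fell in 5 of 16 and rose in 0, also over the list alone. Osr1 was at -1.76 ± 0.82 and Pdgfrb at -1.35 ± 0.71. The list lay at -0.54 ± 0.36 (camera adjusted p = 0.0483, adjusted p = 0.560 with an estimated correlation, exact adjusted p = 0.0145). Camera did not call it without the doubted array of gut 3 (adjusted p = 0.0916) or without pairing (0.0696), nor without gut 1, 2, 3, 6, 7 or 8, where the highest adjusted p was 0.0889.

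Extracellular matrix genes fell in 14 of 24 and rose in 2, and in 15 and 2 when adjusted over the list alone. Sparc was at -1.22 ± 0.40 (n = 9) and Lama2 at -1.56 ± 0.89. The basement membrane collagens Col4a1 and Col4a2 rose by 1.32 ± 1.08 and 1.42 ± 1.26, calls that ended with the hybridisation controls as a covariate (1.18 and 1.35). As a group they lay at -0.75 ± 0.66, below other genes in 8 of 9 guts (camera adjusted p = 3.2e-04, adjusted p = 0.595 with an estimated correlation, exact adjusted p = 0.0361). Matrix proteases and their inhibitors fell in 8 of 14 and rose in 1, and in 10 and 2 when adjusted over the list alone. Mmp2 fell by 1.21 ± 0.71 and Mmp11 fell by 1.29 ± 0.71, with gut 1 at 0.26. The list lay at -0.70 ± 0.35 (camera adjusted p = 0.00652, adjusted p = 0.367 with an estimated correlation, exact adjusted p = 0.0145). The gut mesenchyme list, at -0.54 ± 0.36, moved in the same direction as both, and so did the ribosomal protein list, at -1.01 ± 0.33. Of 25 genes of axon guidance and adhesion, 5 rose and 10 fell, and 5 and 13 when adjusted over the list alone. The netrin receptor genes Unc5c and Dcc rose by 1.27 ± 0.56 and 1.03 ± 0.63 (Dcc by 1.66 with the most reproducible probe set), and Epha4 and Sema3e were at -1.26 ± 0.44 and -1.23 ± 0.45. As a group they lay at -0.37 ± 0.28, below other genes in 7 of 9 guts (camera adjusted p = 0.0456, adjusted p = 0.560 with an estimated correlation, exact adjusted p = 0.0445). Camera did not call it without pairing (adjusted p = 0.0576), nor without gut 2, 3, 5, 6, 7 or 9, where the highest adjusted p was 0.0937. The axon guidance list, too, moved in the direction of the ribosomal protein list.

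Genes of dividing cells were not called as lists. Of 21 genes of the G2/M phase 0 passed limma's test, and of 24 genes of DNA replication 0 rose and 1 fell, or 0 adjusted over each list alone. Their camera adjusted p was 0.690 and 0.370. Gut 1 lay apart in the G2/M list, at 2.54 against -1.14 to 0.17 in the other guts. Of 26 gut epithelium genes 1 rose and 0 fell, also over the list alone (camera adjusted p = 0.920). That gene was Krt19, which mesothelium also expresses, at 1.58 ± 0.51 (n = 9). Epcam, of epithelium, was at -0.27 ± 0.95, and Acta2, of smooth muscle, at -0.80 ± 1.06 (adjusted p = 0.0731). Acta2 passed without gut 1 (-0.97) or gut 9 (-0.99) and with the hybridisation controls as a covariate (-1.30). Smooth muscle genes rose in 2 and fell in 2 of 15, also over the list alone (camera adjusted p = 0.560), and gut 1 lay at 1.60 against -0.93 to 0.24 in the other guts. Of 18 endothelium genes 3 rose and 1 fell, and 3 and 0 when adjusted over the list alone (0.560). Of 17 macrophage and leukocyte genes 2 rose and 2 fell, and 1 and 2 over the list alone (0.920). Of 9 mesothelium genes 2 rose and 1 fell, also over the list alone (0.577).

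Over all 37 lists camera called 11, 3 up and 8 down, and with an estimated correlation it called 0, where 5 passed an unadjusted p of 0.05. Fry called 16. The exact test called 13, 4 up and 9 down, which included all 11 of camera. When the signs of whole guts were changed at random, 14 of 100 draws, the real one included, called as many lists with camera, so chance is not excluded for the number of lists.

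**Figure D2:**
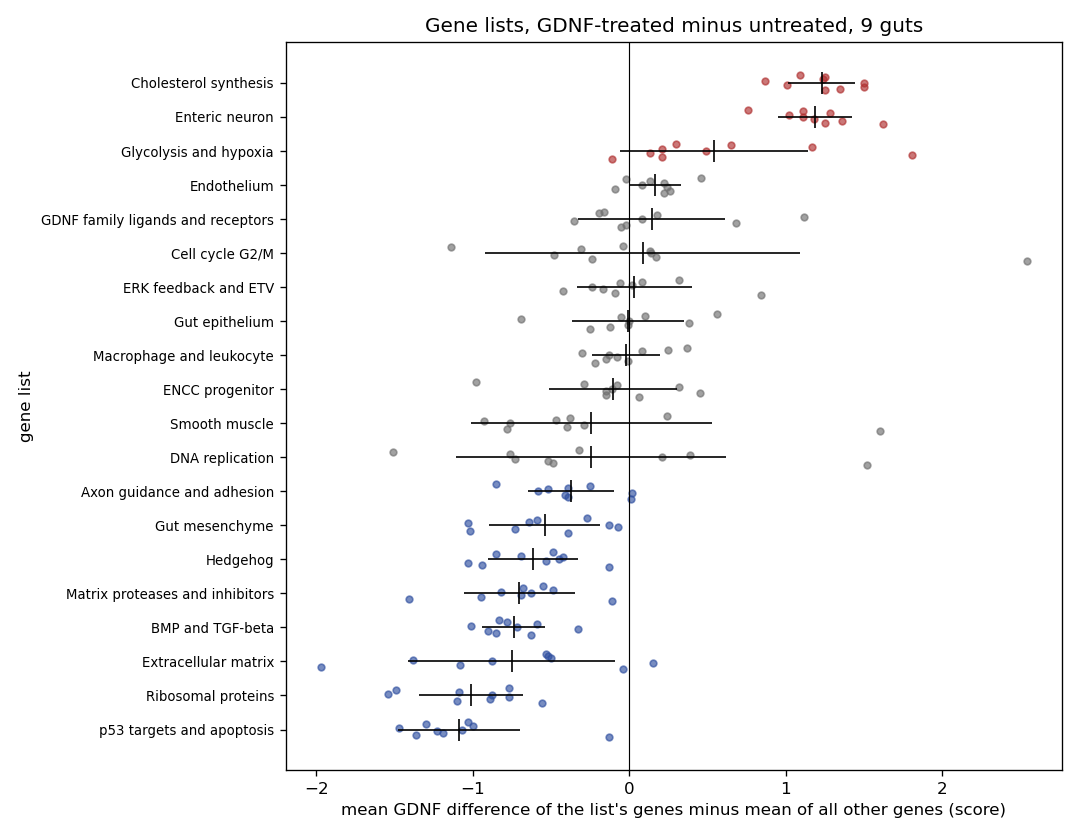
Mean GDNF difference of the genes of each list minus the mean of all other genes (x axis, score units) for selected gene lists (y axis). Points are the 9 guts and bars the mean and SD; red and blue lists were called up and down by camera and grey lists were not. Cholesterol synthesis and enteric neuron genes lie above 0 in all 9 guts.

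The second comparison asked which genes set ENCCs apart from the whole gut. Neural crest and neuron genes were higher in ENCCs, and genes of epithelium, endothelium, macrophages, mesothelium and Hedgehog signalling were lower. Ribosomal protein genes, fixed beforehand as a sign of RNA quality, were lower too, in 8 of 10 with 0 higher, and in all 10 over the list alone. No direct measure of RNA quality was compared between ENCCs and whole gut. Their list lay at -0.78 against other genes (camera adjusted p = 0.00251, adjusted p = 0.0648 with an estimated correlation). Ret was higher by 2.21, with a mean of 0.20 ± 0.59 in ENCCs (SD, n = 4 embryos) and -2.01 ± 0.04 in whole gut (n = 8, limma adjusted p = 3.5e-07). Gfra1 was higher by 2.05, Sox10 by 1.60 and Elavl4, of neurons, by 2.59. With the most reproducible probe set Gfra1 was higher by 1.25 and Sox10 by 2.87. The largest differences were 3.59 for Fam155a, 3.49 for the potassium channel gene Kcnq3 and 3.47 for Npdc1, followed by Map7d1, Cbr3, Cdh19, Cd9, Dpysl3, Mir22hg and Slco3a1 at 3.19 to 3.39. In the other direction, Lgals4 and Fabp2, expressed by intestinal epithelium, were at -3.98 and -3.66 and Gipc2 at -3.92. Akr1c12, Guca2b, Aoc3, Tm4sf5, H2-Q2, Rpia and Akr1c19 were at -3.56 to -3.35. The order is again one of score units and not of fold. Among these 20 genes with the largest differences the highest adjusted p was 7.1e-07, and that of Gfra1 was 1.7e-06.

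Limma called 9837 of 18193 genes (54.1%), 4703 higher and 5134 lower in ENCCs. Of all genes, called or not, 6701 (36.8%) had no overlap between the 4 embryos and the 8 whole guts. Chance would give this in 0.404% of genes if embryos and whole guts had the same spread. The scores of whole guts often varied far less (for Ret, SD 0.04 against 0.59 in embryos), so that share is too low for these scores. Of the called genes 6669 had none, 3124 higher and 3545 lower. All samples lie in batch 2, and the sort, the culture and the genotype of the embryos differ between the groups together with the tissue. Gdnf was higher in ENCCs by 0.98 (adjusted p = 0.00546), a call that ended when all ENCC RNAs were used (0.75). Etv4, Etv5 and Spry4 were higher by 0.82, 1.60 and 1.22. Dusp6 differed by 0.36 (adjusted p = 0.221), with embryo 3 at -1.02, and passed without that embryo (0.73), without the doubted array of gut 3 (0.71) and with all ENCC RNAs (0.89). Ednrb differed by 0.02 (adjusted p = 0.951). Acta2 and Epcam were at -0.97 and -2.21.

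**Figure D3:**
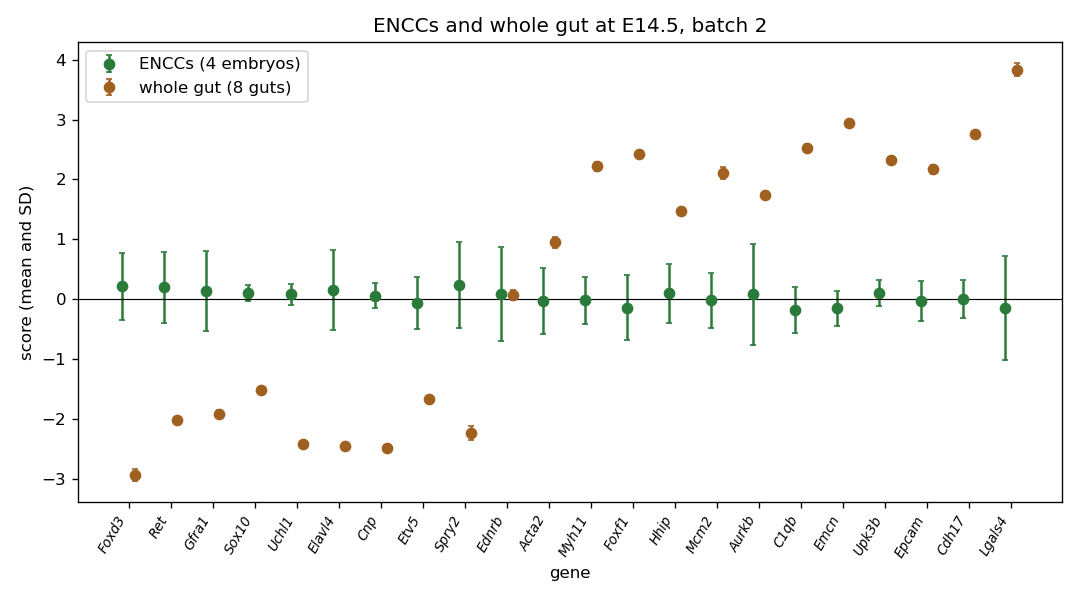
Mean score and SD (y axis) of selected genes (x axis) in ENCCs (green, 4 embryos) and whole gut (brown, 8 guts) of batch 2. The scores were scaled on ENCC arrays; whole gut lies at -2.01 for Ret and 2.17 for Epcam.

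Of 18 ENCC progenitor genes 14 were higher in ENCCs and 0 lower, and of 24 enteric neuron genes 23 and 0, also over each list alone. Foxd3 and Sox2, factors of the neural crest and of progenitors, were higher by 3.15 and 2.26, and the neuronal hydrolase gene Uchl1 by 2.48. Nefm differed by 0.29 and Tlx2 was at -0.48. Both passed without embryo 9 (0.41 and -0.94) and with all ENCC RNAs (0.41 and -0.71). Camera called both lists, at adjusted p = 2.8e-06 and 7.9e-13, and they held with an estimated correlation (0.0292 and 0.0248). Of 16 enteric glia genes 13 were higher and 2 lower, and 14 and 2 when adjusted over the list alone. Cnp was higher by 2.55, and Sostdc1 was lower, at -1.16 (camera adjusted p = 1.8e-04, adjusted p = 0.0561 with an estimated correlation). Of 16 genes of ERK feedback and ETV factors 11 were higher and 0 lower, and 12 and 0 over the list alone. Spry2 was higher by 2.47, and by 1.47 with the most reproducible probe set (camera adjusted p = 1.8e-04, adjusted p = 0.0881 with an estimated correlation). Of 9 GDNF family ligands and receptors 6 were higher and 1 lower, also over the list alone. The ligand gene Nrtn was the lower one, at -1.33 (camera adjusted p = 0.0442, adjusted p = 0.110 with an estimated correlation). Camera did not call that list with all ENCC RNAs (adjusted p = 0.0733) or without embryo 9 (0.0561). Of 17 Hirschsprung disease genes 11 were higher and 4 lower, also over the list alone, with Bbs4 higher by 1.93 and Ece1 at -1.01 (camera adjusted p = 0.0177, adjusted p = 0.0881 with an estimated correlation).

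Markers of several other cell types of the gut were lower in ENCCs, though not those of every type listed. All 26 gut epithelium genes, all 18 endothelium genes and all 9 mesothelium genes were lower, also over each list alone. Cdh17, an epithelial cadherin, was at -2.75, Emcn, of endothelium, at -3.10 and Upk3b, of mesothelium, at -2.22. Of 17 macrophage and leukocyte genes 15 were lower and 1 higher, also over the list alone. The complement genes C1qa and C1qb were at -2.67 and -2.70, and Adgre1 was higher by 1.32, a call that ended without the doubted array of gut 3 (1.07). Camera called these lists at adjusted p = 8.1e-16, 4.1e-10, 1.8e-05 and 2.8e-06, and they held with an estimated correlation (0.0248, 0.00127, 0.0434 and 0.0248). Of 12 Hedgehog genes 10 were lower and 0 higher, also over the list alone. The ligand gene Shh was at -2.11 and Hhip at -1.38 (camera adjusted p = 2.0e-04, 0.0248 with an estimated correlation). Smooth muscle genes were lower in 11 of 15 and higher in 1, also over the list alone, with Mylk at -2.54 and Myh11 at -2.25 (camera adjusted p = 2.7e-04, adjusted p = 0.0652 with an estimated correlation). Gut mesenchyme genes were lower in 11 of 16 and higher in 1, and 12 and 1 over the list alone. Foxf1 was at -2.55, and Prrx1 was higher by 1.14 (list called by camera, adjusted p = 0.0572 with an estimated correlation, fry adjusted p = 3.2e-07). Erythroid genes were lower in 7 of 11 and higher in 0 (camera adjusted p = 0.0200, adjusted p = 0.244 with an estimated correlation). Of 6 genes of interstitial cells of Cajal 5 were lower and 1 higher, and camera did not call the list (adjusted p = 0.0516), nor that of the melanocyte lineage, with 2 of 8 lower and 1 higher (0.675). Genes of Schwann cell precursors, a type that also comes from the neural crest, were higher in 9 of 10 and lower in 1 (list called by camera, adjusted p = 0.0881 with an estimated correlation). These counts were the same over each list alone.

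Genes of dividing cells were lower in ENCCs as well. All 21 genes of the G2/M phase were lower, also over the list alone, with Aurkb at -1.65 and Top2a at -1.11 (camera adjusted p = 2.8e-06, adjusted p = 0.271 with an estimated correlation). Of 24 genes of DNA replication 23 were lower and 0 higher, also over the list alone. Mcm2 was at -2.12 and Rfc4 at -1.73 (camera adjusted p = 3.0e-09, adjusted p = 0.110 with an estimated correlation). The ribosomal protein list lay lower in the same samples (-0.78). Over all 37 lists camera called 27, 15 higher and 12 lower in ENCCs, and 7 held with an estimated correlation.

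Untreated and treated ENCCs were also set against whole gut apart, as the series design asks. Elavl3, of neurons, was higher by 1.03 in untreated cells (n = 4 against 8, limma adjusted p = 0.00159) and by 2.98 in treated cells (adjusted p = 1.4e-08). Vip was higher by 1.16 and by 2.84, and Ret by 1.80 and by 2.61. Sox10 was higher by 1.66 and by 1.55, and Epcam lay at -2.06 and -2.36. Limma called 5935 genes for untreated cells, 2715 higher and 3220 lower than in whole gut, and 7468 for treated cells, 3734 higher and 3734 lower. The fits share the 8 whole guts, and a gene called in 1 of them is not thereby shown to differ between treated and untreated cells, which the paired test addresses.

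The third question was which genes of ENCCs depend on GDNF. Of the 4703 genes higher in ENCCs than in whole gut, 1850 rose with GDNF, 602 fell and 2251 were not called. Of the 5134 genes lower in ENCCs, 630 rose, 929 fell and 3575 were not called. Genes that rose were higher in ENCCs more often than independent lists give, with 858.5 in place of 1850 (odds ratio 5.30). Genes that fell were lower in ENCCs more often (678.4 in place of 929, odds ratio 1.73, Fisher's exact test p = 1.6e-32). For genes that fell and were higher in ENCCs the odds ratio was 0.952 (p = 0.342). With GDNF calls from guts 1, 4, 5, 6 and 7, which do not enter the comparison with whole gut, 1112 genes rose and were higher in ENCCs, against 445.9 for independent lists (odds ratio 6.50, Fisher's exact test p = 1.9e-279). Those guts take away only the noise that shared wells would bring. Each ENCC value set against whole gut was the mean of a treated and an untreated well. A change with GDNF therefore moves that value in the same direction, whichever guts gave the GDNF calls. The overlap and the correlation across genes are thus partly built in, and how far was not tested. The overlap was not taken with calls of untreated cells alone. Genes are not independent replicates, so the p-values of the overlap overstate the evidence. Across all genes the 2 differences correlated with r = 0.221 and rho = 0.211. With the signs of whole guts changed at random, 5 of 100 draws, the real one included, gave a correlation as large, so chance is not excluded for it. The odds ratios were not set against sign changes, so chance is not excluded for the overlap either.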

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

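The tests of labelled RNA, of degraded RNA, of other cell types and of unannotated RNA in this part were chosen only after the results were seen, whereas the counts over other splits and sign changes were fixed beforehand. Of 346 groups of 4 to 10 samples tested for 1 sample far from the others, 25 had one, against 17.3 that chance gives at about 1 in 20.

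Limma called 5725 genes between treated and untreated wells. The difference may reflect the treatment, but technical sources were weighed first. A different amount of labelled RNA in treated wells would leave few calls at a hybridisation control difference of 0, and 4592 genes (80.2% of the count) were called there. Fewer cells of all other gut cell types would lower mesenchyme and epithelium genes alike. The shift of the mesenchyme list minus that of the epithelium list was -0.53 (SD 0.28, below 0 in 9 of 9 guts, exact p = 0.00391). This does not decide it, since all 26 epithelium genes were already lower in ENCCs than in whole gut. The scores keep no signal over background, so whether these genes could fall further is not known. More degraded RNA in treated wells would raise the 3′ control probe sets of Actb, Gapdh, Tfrc and Pcx against their 5′ sets, and the mean over these 4 transcripts was -0.34 (SD 0.43, above 0 in 2 of 9 guts, exact p = 0.0625), which does not decide it. RNA quality stays open, with ribosomal protein genes at -1.01 in 9 of 9 guts. So do the scaling of the deposited values and any handling of the wells that went with the treatment. A lower share of other gut cells, of mesenchyme alone or of several types, stays open too. So does a changed share of neurons among the sorted cells, which no test addressed.

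The control probe set for the B1 repeat, a short interspersed element of the mouse genome, stood out among the control probe sets, which no comparison of the report uses. It rose with GDNF by 1.92 ± 0.30 (SD, n = 9, 9 of 9 guts up, exact p = 0.00391, limma adjusted p = 1.5e-04 over 64 control probe sets), with untreated wells between -1.77 and -0.46 and treated wells between 0.26 and 1.31. The 2 probe sets for the B2 repeat moved the other way. They lay at -0.90 ± 0.52 (0 of 9 guts up, exact p = 0.00391, limma adjusted p = 0.0949) and -0.55 ± 0.37 (1 of 9 guts up, exact p = 0.00781, limma adjusted p = 0.140). More unspliced or other unannotated RNA would raise probe sets without a single gene name above named ones, and their median was above in 0 of 9 guts. This does not decide it, since the set includes probe sets with several gene names. Which of its probe sets read unspliced RNA is not known. A different amount of labelled RNA would leave no B1 difference at a hybridisation control difference of 0, where it was 1.87 (SE 0.13). A change in transcripts that carry B1 stays a hypothesis, since it rests on 1 probe set.

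Xist, expressed from the inactive X chromosome of females, and the mean of 3 Y-linked genes were both above 0 in 5 of 8 whole guts and in 0 of 25 ENCC arrays. The scores are relative to the ENCC arrays, which sets where 0 lies, and no explanation was tested.

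The array of the untreated well of gut 3 in batch 2 had a relative scale before ranking of 1.502, where the 6 other arrays of that set lay at 0.844 to 0.997, and the same RNA correlated between batches at 0.117, against 0.247 to 0.325 for the others. Its batch 1 array correlated at 0.388 with another untreated RNA of batch 2. In the sex genes the doubted array went with gut 3. Xist lay at -0.91 and the Y-linked mean at 0.75, against -1.29 and 0.94 for the same RNA in batch 1. In the untreated wells of guts 2, 8 and 9 in batch 2, Xist was above 0 and the Y-linked mean below 0. Without that array 5883 genes were called for GDNF.

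Whole gut 4 lay apart from the other 7 whole guts in Mir22hg (-3.54), Guca2b (2.46), Gdnf (-0.21), Nefm (0.24), Sst (0.10), Jun (-0.95), Mcm2 (2.32) and C1qa (2.61). Without it, 9548 genes were called between ENCCs and whole gut. Among the GDNF differences, gut 1 lay apart in Dusp6 (4.42), Ccnd1 (-0.27), Mmp11 (0.26) and Fzd2 (0.09), and in the lists of p53 targets (-0.13), Hox genes (0.81), the G2/M phase (2.54) and smooth muscle (1.60). Gut 2 lay apart in Spred3 (0.80), gut 5 in Hoxd9 (-3.04) and gut 6 in Hsd17b7 (-2.09). Among the ENCC embryos of batch 2, embryo 3 lay apart in Dusp6 (-1.02), embryo 9 in Nefm (-0.32), and embryo 2 in Klf4 (-0.91) and Hoxd3 (1.06).

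Of 10092 probe sets without a single gene name, which the comparisons leave out, 857 passed limma's test for GDNF, 391 higher and 466 lower. This is 8.49%, against 30.1% of the named probe sets.

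For 4 counts of called genes, of 100 drawn splits or sign changes only the real one (1 of 100) gave as many. The real count and the highest other were 5725 and 1318 for GDNF, 9837 and 3073 for ENCCs against whole gut, 7752 and 2645 for untreated cells and 9281 and 10 for treated cells, the last 2 in fits of the 2 groups alone. Chance could thus be excluded for the GDNF count. For the lists of ENCCs against whole gut, 3 of 100 splits were as large (27 lists, highest other 28). The splits cannot decide for the results against whole gut. Scaling on ENCC arrays sets all whole guts apart together, so a split that mixes the groups widens the spread and loses calls. Chance could not be excluded for the number of lists with GDNF, where 14 of 100 sign changes called as many (11 lists, highest other 16). Nor could it be for the correlation across genes between the GDNF difference and the ENCC difference, where 5 of 100 were as large (0.221, highest other 0.266).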

How the results depend on the processing

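The fits with the most reproducible probe set, without the doubted array of gut 3, with the hybridisation control covariate, with a robust spread without trend, on guts 1, 4, 5, 6 and 7 for the count of genes (for the overlap it was planned), with a minimum score difference, with the exact test of lists, and with samples left out for the ENCC lists were chosen after seeing the data. For GDNF, 5725 genes were called. Testing each probe set gave 10521 calls, from more tests. Batch 2 alone, which has fewer guts and leaves out the batch 1 arrays, gave 0 (3516 at an unadjusted p of 0.05), guts 1, 4, 5, 6 and 7 gave 2467, and a score difference of at least 1 left 3637 by its construction. The other settings gave 4592 to 6230. Among them, the most reproducible probe set gave 6208, a choice that favours probe sets with a large GDNF difference. Without the block by gut, that is without pairing, 4890 genes were called, of which 4737 (96.9%) were shared with 1 sign, 9 of 120 named genes lost their call, and camera called 9 lists, without the axon guidance and gut mesenchyme lists. With 1 gut left out, 5029 (without gut 8) to 5909 (without gut 1) genes and 8 to 11 lists were called. Fry called 16 lists, the exact test 13 and camera without the doubted array 10. With an estimated correlation 0 of the 11 lists passed (5 at an unadjusted p of 0.05). For ENCCs against whole gut, with 9837 calls, each probe set gave 17561 and a difference of at least 1 left 5226. The other settings gave 7474 to 10779. For untreated and treated cells, with 5935 and 7468 calls, fits of the 2 groups alone gave 7752 and 9281, and all RNAs 8515 and 9870. With 1 sample left out the counts were 9316 to 10474, 5240 to 6612 for untreated cells, 6916 to 7385 for treated cells and 26 to 28 lists. With an estimated correlation 7 of the 27 lists were called. The odds ratio of the overlap was 5.30, 6.50 and 5.94 in all guts, in guts 1, 4, 5, 6 and 7 and without the doubted array. In each of these settings the overlap is partly built in, since the ENCC values include treated wells. The correlation between batches was 0.296 over probe sets and 0.350 over genes. Of 120 named genes for GDNF and 97 for ENCCs against whole gut, 0 had a reversed call in the settings run with limma. In batch 2 alone all 92 called GDNF genes lost their call but had the same sign, 83 of them within 1.5 times the size, and in guts 1, 4, 5, 6 and 7 alone 29 lost it, with all 92 of the same sign and within 1.5 times. Planned but not run were the filter on dim genes and the limits of fold, which the scores cannot give, and quantile normalisation, which moves nothing because all arrays share 1 distribution. The scores keep no signal over background, so what brightness limits cannot be given. Where no cause is named here, the cause was not tested.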

Other observations

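The gene groups below were fixed before the data were examined, and the exact sign change test of lists was chosen only after the results were seen. Among genes of GDNF-treated against untreated ENCCs, immediate early genes moved both ways. Of 20 measured, 2 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.462). Nr4a1 rose by 1.62 ± 0.59 (SD, n = 9) and Arc by 1.43 ± 0.58, while Jun was at -1.62 ± 0.55 and Btg2 at -1.58 ± 0.41. Of 24 Hox genes 4 rose and 4 fell, also over the list alone. Hoxb5 rose by 1.70 ± 0.65 and Hoxb4 by 1.39 ± 0.56, and Hoxd9 and Hoxd8 were at -1.28 ± 0.80 and -1.26 ± 0.76 (camera adjusted p = 0.560). Of 17 Notch genes 3 rose and 5 fell, also over the list alone. The ligand gene Jag2 rose by 1.46 ± 0.65, the ligand gene Jag1 was at -1.28 ± 0.79 and the effector Rbpj at -1.51 ± 0.82, or -0.48 in batch 2 alone (camera adjusted p = 0.560). Of 16 WNT genes 4 rose and 2 fell, also over the list alone. Rspo3, which strengthens WNT signalling, rose by 1.57 ± 0.37, and the receptor gene Fzd2 fell by 1.41 ± 0.67 (camera adjusted p = 0.731). Of 16 enteric glia genes 6 rose and 1 fell, also over the list alone. Fabp7 rose by 1.60 ± 0.39 and Apoe by 1.48 ± 0.94 (0.87 in batch 2 alone), and Cdh19 fell by 0.91 ± 0.64, a call that ended without pairing, at -0.90, and with the hybridisation controls as a covariate, at -0.60 (camera adjusted p of the list 0.453). Of 8 long-standing reference transcripts 2 rose and 3 fell, also over the list alone. Ywhaz rose by 1.05 ± 0.40 and Rplp0 fell by 1.45 ± 0.58, and the list shifted down by the exact test (adjusted p = 0.0145) and not by camera (0.560).

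Against whole gut, ENCCs had 11 of 21 transmitter and neuropeptide genes higher and 2 lower, also over the list alone. The peptide gene Gal was higher by 2.57 and Nos1, which makes nitric oxide, by 1.99 (3.39 with the most reproducible probe set), and Ddc, of amine synthesis, was at -1.17 (n = 4 against 8, camera adjusted p = 0.00120, adjusted p = 0.0767 with an estimated correlation). Of 20 immediate early genes 12 were higher and 4 lower, also over the list alone. Fos was higher by 2.17 and Jun by 1.28, and Klf4 and Klf2 were at -1.59 and -1.46 (camera adjusted p = 0.0331, adjusted p = 0.217 with an estimated correlation). Of 24 Hox genes 6 were higher and 9 lower, and 7 and 9 over the list alone. Hoxd3 was higher by 1.82, and Hoxd10 and Hoxc8 were at -2.07 and -2.06 (camera adjusted p = 0.656).

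In the ENCC arrays of gut 5, Xist lay at -1.84 and -2.20 and the mean of the Y-linked genes at -0.42 and -0.59, so that both were low in both wells. In gut 3, Xist lay at -1.29 and -1.74 in batch 1 and at -0.91 and -1.88 in batch 2, with the Y-linked mean at 0.94, 1.43, 0.75 and 1.30. In all ENCC arrays of the other guts Xist was above 0 and the Y-linked mean below 0.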
